A study of Nothobranchius furzeri with 10 samples.

How the data were processed

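Skin RNA of male GRZ killifish was measured in 10 libraries of 1 group, made with a TruSeq RNA kit per the labels' protocols. Per the submitters' processing notes, the tools included bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build and the annotation are not given in the sources used here. The authors deposited a table of whole-number counts per gene and a table of RPKM (reads per kilobase of gene and per 1e6 counts) for the same 26739 genes and 10 libraries. Columns were matched to libraries by their titles. Replicate numbers follow the order of the records and name a library only. The count table had 4046 genes at 0 in all libraries.

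The deposited RPKM values carry a divisor error. Dividing the deposited counts by the RPKM and by the library's own total should give 1 length per gene, but across libraries the implied length had a median coefficient of variation of 22.4% over 4151 genes with at least 500 counts and over 5 RPKM in each library. When the 10 totals were instead cycled down the rows of the table and on through its columns, the largest coefficient of variation over these genes was 0.00662%. With this divisor, 99.4% of 1879 genes with a highest RPKM over 50 had an implied length within 0.05 of a whole number. The deposited RPKM thus used another library's total in 90.0% of cells and differs from the value with the own total by a factor of 0.625 to 1.60. Restored RPKM, with each cell rescaled to its own library's total, was used for the level per length of the most abundant genes and as an alternative setting. Counts do not have this error. They were used to rank genes by level and, apart from alternative settings, for everything compared across libraries. The median SD of log2(RPKM + 0.1) was 0.46 as deposited and 0.34 restored.

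Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filter on expression, which with 1 group asks for its minimum in all 10 libraries and left 16829 genes. Library sizes were scaled by TMM, with factors from 0.944 to 1.08. log2 CPM used a prior count of 2. Excess spread was tested by setting each gene's quasi-dispersion, from a fit with an intercept only, against a robust trend over abundance and taking a one-sided F test with Benjamini-Hochberg adjustment at 0.05. Restored or deposited RPKM were tested as log2 values with the same trend method. DESeq2 1.42.0 gave the dispersion outliers. Modules came from average linkage on 1 minus Pearson's r of log2 CPM, with the tree divided at a height of 0.4 and modules of at least 10 genes. Principal components were taken from centred log2 CPM. Shares of counts in single libraries have exact binomial (Clopper-Pearson) intervals at 95%, and a count of 0 was taken to allow up to 3 counts. Correlations across libraries have two-sided permutation tests with 100000 resamples, and those of component 1 an exact permutation within the 2 sets of libraries that it parts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for these steps.

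The test of excess spread was tested on simulated counts. With 1 spread for all genes it called 71 of 95 genes given an added SD of 1, 63 of 63 given an added SD of 3 and 6 of 16431 unchanged genes. With spread differing between genes it called 0 of 92 and 0 of 57. Each added SD was given to 100 genes, and these counts leave out those that the filter on expression removed. The estimated prior degrees of freedom were 3.07 in the data, 288 in the first simulation and 3.70 in the second. The count of genes that part the libraries in 2 sets, run on 16829 simulated genes, found 73 of 100 genes with a 2-fold change and 100 of 100 with a 4-fold change, and 133 of 16569 unchanged genes. The module step, run on the same 16829 genes, placed 60 of 60 simulated members in 1 module with 0 others. In this simulation all genes shared 1 dispersion, below the common dispersion of the data, and unchanged genes varied independently. Recovery in the data may therefore be lower and false joining of genes more frequent. The 0 others say little about joining among widely varying genes that share other patterns.

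The tests, the named-gene rule, the 33 gene lists and most alternatives were fixed before the data were examined. The rule named the 10 most abundant genes, the genes past the threshold with the largest ratio to the trend, the 5 steadiest genes at 50 CPM or more, members of the fixed lists and module centres, and skipped rows without a gene symbol. As 0 identifiers matched the reference gene table (assembly NfurGRZ-RIMD1), the 10 most abundant and 5 steadiest rows were all skipped by that rule, and the 4 identifiers printed were chosen after their values were seen. Spread, coherence and covariation of the lists, fast against slow muscle genes and the levels of stress lists were not analysed here for the same reason. Chosen after the data were seen were the RPKM restoration, the low-count filter in 3 libraries, the first component with each library left out, the 2 sets of sample codes as a covariate, the threshold of 1 on the SD, the modules built on it, the separation of the libraries by sample code, the test of component 1 within these sets and the comparison of module shares between libraries of like depth.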

Results

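RNA was sequenced from the skin of male turquoise killifish, Nothobranchius furzeri, a short-lived annual fish kept as a laboratory model of ageing. The fish belonged to the inbred GRZ strain and were 10 weeks old. All 10 libraries carried the same swim-tunnel label, a device in which fish swim against a current, and form 1 group without an unexercised group in the samples used here. The design therefore gives levels and the spread between libraries, and no contrast between conditions. The labels do not say that each library came from a separate fish, so the spread between libraries may be partly technical.

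Assigned counts averaged 30697867 ± 4734180 per library (SD, n = 10) and ranged from 23206247 to 37149070. A mean of 21382 ± 184 genes (SD, n = 10) of the 26739 in the table had at least 1 count in a library. A gene with 0 counts could have been present at up to 0.0808 counts per 1e6 counts (CPM) in the deepest library and up to 0.129 CPM in the shallowest, taking 3 counts as the limit. Such limits and the binomial intervals below cover counting error only. The smallest chi-square per degree of freedom between a pair of libraries was 35.5, between replicates 2 and 5, so no pair agreed within sampling noise, as 1 library deposited again would. This does not show that the libraries came from separate fish.

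The gene identifiers are not paired with gene names in the files, and 0 of them matched the reference gene table used here. Genes are therefore described by level and by how they varied together, and the 33 gene lists chosen for skin, muscle, blood, immune and stress programmes could not be read out.

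A small set of genes supplied a large part of the skin RNA. The 10 genes with the highest mean CPM took 16.6% ± 1.36 of all counts (SD, n = 10), from 14.5% in replicate 3 (exact 95% binomial interval 14.49% to 14.52%) to 18.6% in replicate 2 (18.63% to 18.66%). The 100 most abundant genes took 37.0% ± 2.06 (SD, n = 10). Genes at 1000 CPM or more numbered 125 and held 39.7% ± 2.15 of the counts, whereas the 6239 genes at 1 to 10 CPM held 2.88% ± 0.234. The most abundant gene, Nfu_g_1_002091, reached 39198 ± 7217 CPM (SD, n = 10) and alone made up 3.88% ± 0.647 of the counts. The next, Nfu_g_1_001437, reached 24851 ± 4747 CPM. Their order by level per length was the same and the gap wider, at 21388 ± 3569 and 2883 ± 491 reads per kilobase and per 1e6 counts (RPKM, SD, n = 10, restored as described for the processing). Both differed less than 2-fold between the highest and the lowest library, by 1.87-fold and 1.84-fold.

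**Figure D1:**
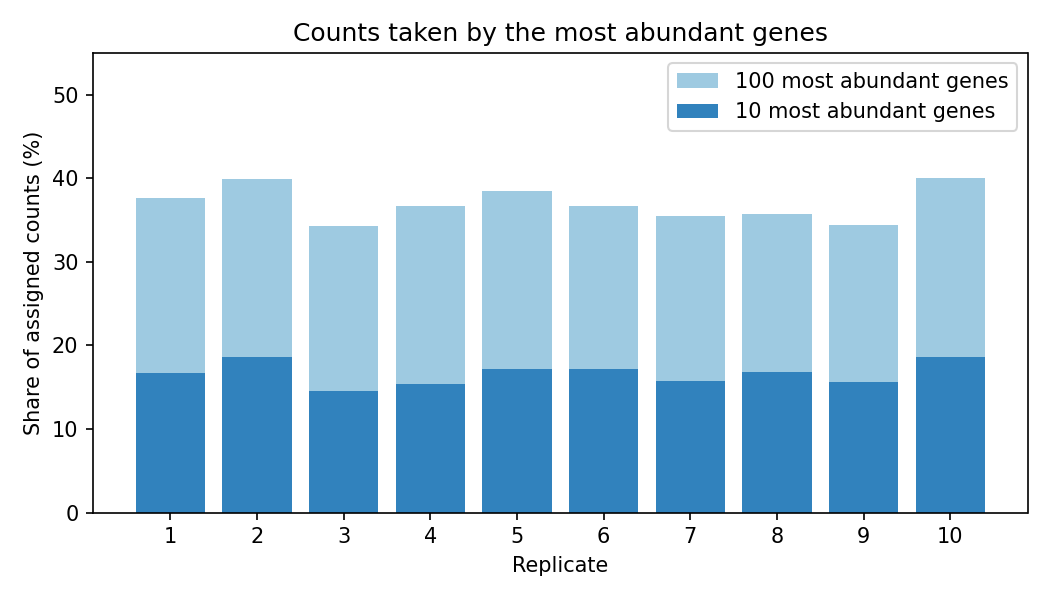
Share of assigned counts (%, vertical axis) in each of the 10 libraries (replicate, horizontal axis); dark bars show the 10 most abundant genes and light bars, drawn behind them from 0, the 100 most abundant. The dark bars lie between 14.5% and 18.6% and the light bars between 34.3% and 40.1%.

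The median SD of log2 CPM over the 16829 tested genes was 0.34, and 25% of the genes had an SD under 0.23. The biological coefficient of variation, a relative spread beyond counting noise fitted in common to all genes, was 0.325. It is not the spread of the median gene, for which 1 SD was 1.27-fold. The typical spread was larger in rarer genes, with a median SD of 0.24 at 1000 CPM or more and 0.42 at 1 to 10 CPM. An SD of at least 1 was reached by 543 genes (3.23%), of at least 2 by 37 genes and of at least 3 by 7 genes. The count of 543 depends on the genes admitted and on the main axis between libraries. It was 1576 of 22693 genes without a filter on low counts, 1317 of 19025 with the filter asked of 3 libraries, and 361 with component 1 as a covariate. The widest relative to genes of like abundance were Nfu_g_1_006412 and Nfu_g_1_013388, singled out after their values were seen. The first averaged 832 ± 1143 CPM (SD, n = 10) and ran from 2.94 CPM (73 counts) in replicate 10 to 3718 CPM (104440 counts) in replicate 3, a 1265-fold range. The second ran from 2.21 CPM (55 counts) to 1480 CPM (41573 counts) in the same pair of libraries.

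The planned question was which genes varied more than genes of like abundance. With edgeR's quasi-likelihood fit and a one-sided F test, 0 of 16829 genes passed a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p being 0.939. At an unadjusted p of 0.05 there were 696, and 931 with the 2 sets of sample codes (74 to 78 and 80 to 84) as a covariate or 1036 with component 1 as a covariate. The first count lies under the share of 0.05 of genes that chance alone would pass, and the others lie somewhat above it. DESeq2's rule for dispersion outliers named 110 genes. The quasi-dispersions of Nfu_g_1_006412 and Nfu_g_1_013388 were 149 and 120 times the trend, with adjusted p of 0.939 for both (edgeR). On simulated counts in which genes differed in spread, the same test called 0 of 92 genes with an added SD of 1. It called 0 of 57 with an added SD of 3. Both counts take only genes that passed the filter. The count of 0 is thus a limit of the test with these spreads and not a finding of even expression.

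Genes with a wide spread moved in groups. Clustering of the 543 genes with an SD of at least 1, a set chosen after the planned test had called 0 genes, placed 504 in 11 modules of at least 10 genes. Module 1, with 170 genes and a mean pairwise r of 0.87 across libraries, took 2.25% of the counts in replicate 3 (exact 95% binomial interval 2.249% to 2.260%), 1.18% in replicate 8 and 0.946% in replicate 9. It took 0.0850% in replicate 10 (0.0839% to 0.0862%), 0.101% in replicate 7 and 0.102% in replicate 1. Its mean share was 0.636% ± 0.680 (SD, n = 10). The median member of module 1 spanned a 16.3-fold range between libraries. Both genes with the widest spread belonged to it. Without replicate 3 the largest module had 109 genes, 107 of them members of module 1. Genes dropped by the filter could not enter a module. Kept genes held 28546324 of 29247549 counts in replicate 3 and 36507441 of 37149070 in replicate 8. They held 26297523 of 26329657 in replicate 10. Genes well counted in some libraries only were thus left out, so the modules may understate such differences.

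Module 3, with 88 genes, stood high in 1 library. It took 0.248% of the counts in replicate 8 (0.2468% to 0.2500%) and from 0.0151% to 0.0308% in the other 9. Module 5, with 21 genes, was lowest in the same library, at 0.00363% of the counts (0.00344% to 0.00383%) against 0.154% in replicate 7, where it was highest. Module 6, with 18 genes, was also lowest in replicate 8, at 0.0126%, and highest in replicate 5, at 0.318%. Modules 2 and 4, with 93 and 55 genes, moved in opposite directions and parted the libraries at the gap in their sample codes, which run from 74 to 78 and from 80 to 84. Module 2 took 0.0702% to 0.116% of the counts in replicates 1 to 5 and 0.316% to 0.460% in replicates 6 to 10. Module 4 took 0.149% to 0.313% in replicates 1 to 5 and 0.0486% to 0.0696% in replicates 6 to 10. The members were chosen for their spread and grouped by their correlation, so the size of r within a module is no test.

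**Figure D2:**
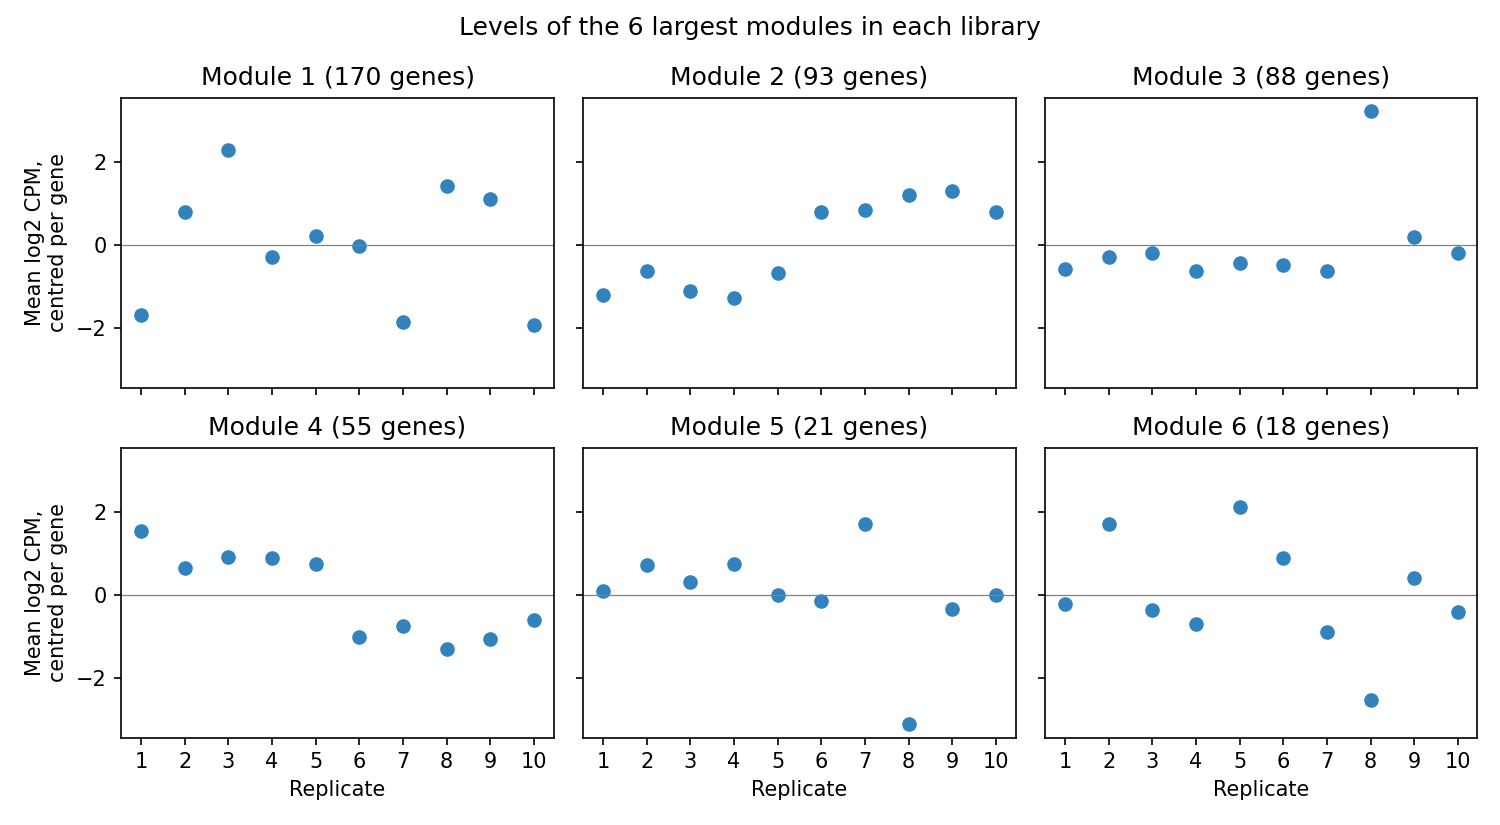
Level of the 6 largest modules (mean over members of log2 CPM centred on each gene's mean, vertical axis) in each of the 10 libraries (replicate, horizontal axis); each point is 1 library. Module 3 stands at 3.21 in replicate 8 and at 0.20 or less in the other libraries, and module 5 stands at -3.11 in replicate 8.

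The libraries differed along a main axis that took 42.7% of the variance of log2 CPM, with 21.7% on the second component and 10.1% on the third. The highest share of a first component in 100 tables with each gene's values shuffled was 12.4%. Component 1 parted the libraries into 2 sets of 5, with scores from -55.3 to -25.1 in replicates 1 to 5 and from 23.3 to 63.3 in replicates 6 to 10. Because of this gap no pooled correlation was taken for it, and its relation to library size and to the share of the 100 most abundant genes was tested with the 2 sets as a block, by an exact two-sided permutation within the sets (14400 rearrangements, 2 relations). With log2 library size the within-set Pearson r was 0.16 (exact permutation p = 0.680, Benjamini-Hochberg adjusted 0.960) and rho was 0.050 (exact permutation p = 0.942, adjusted 0.942). With the share of the 100 most abundant genes r was -0.020 (exact permutation p = 0.960, adjusted 0.960) and rho was 0.15 (exact permutation p = 0.735, adjusted 0.942). Without the 2 libraries farthest from their set's mean, r was -0.091 and 0.22. Library totals in the 2 sets differed by less than their spread (exact permutation p = 0.659, n = 5 each). Component 2 showed no relation past the threshold with either. Its Pearson r with log2 library size was 0.079 (permutation p = 0.830, Benjamini-Hochberg adjusted 0.830 over 2 relations) and Spearman's rho was 0.13 (permutation p = 0.736, adjusted 0.736). Its r with the share of the 100 most abundant genes was -0.38 (permutation p = 0.283, adjusted 0.566) and rho was -0.43 (permutation p = 0.221, adjusted 0.442). Without the 2 libraries farthest from the median of component 2, r was -0.28 and -0.38.

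**Figure D3:**
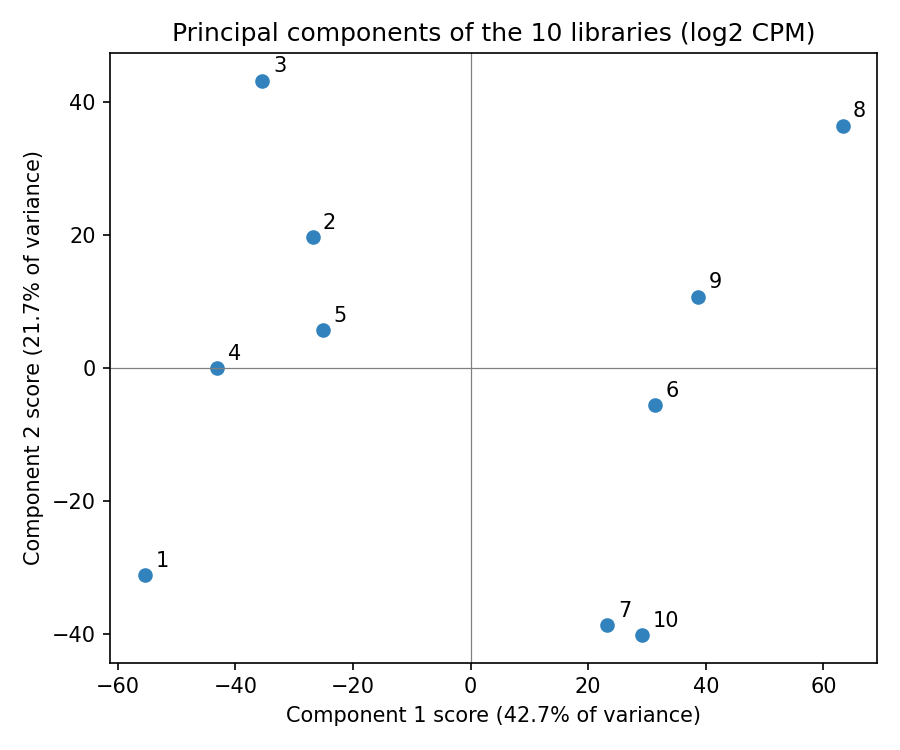
Scores of the 10 libraries on principal components 1 (horizontal axis) and 2 (vertical axis) of centred log2 CPM, in units of log2 CPM summed over genes; each point is 1 library with its replicate number. Replicates 1 to 5 lie at -25.1 or below on component 1 and replicates 6 to 10 at 23.3 or above.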

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

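The comparison by depth for the module high in replicate 8 was chosen after the result was seen, as were the lists chosen by replicate 8. Of 18 library-level measures, 2 passed Dixon's 95% limit, both in replicate 8 and both scores of modules. Chance passes the limit in about 1 of 20 sets of values, but this rate does not apply to module scores, since genes picked for a wide spread and extreme in 1 library form such a module by construction. Of the 7 measures that are not module scores, 0 passed.

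Replicate 8 lay far above the other libraries in the score of module 3, with a gap to the next library of 0.785 of the whole range. Against each of the 2 libraries with totals within 5% of its own, replicate 8 had at least 14.2 times the module's unscaled share of counts. This lies beyond the 1.14-fold range of the scaling factors. The module was flagged for standing high in replicate 8 alone, so this outcome was set by that choice and is no separate test of depth or scaling. A cell population that is also present at a low share in the other libraries may be a candidate source, since members had a mean pairwise r of 0.217 over the other 9 libraries, against 0.0225 at the 95th percentile of 10000 random lists matched on level. Members had been grouped on those libraries as well; of 248 genes at 2 or more log2 units above the median of the others in replicate 8, all 88 members included, the 160 outside the module gave 0.176 against 0.0115, and the 109 of these in no module gave 0.144 against 0.0164. The random lists were not matched on spread or on direction in replicate 8. This correlation can therefore also follow other differences between the libraries, such as those on component 1, where replicate 8 scored highest at 63.3. It does not single out a cell population. No cell type could be named, and a difference in dissection or in the animal stays open and untested.

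Replicate 8 lay below the other libraries in the score of module 5, with a gap of 0.574 of the range.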

How the results depend on the processing

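The restored RPKM, the filter in 3 libraries, the first component with each library left out, the SD threshold, modules, separation counts and the covariate for the 2 runs of sample codes were chosen after the data were seen. No paired analysis was possible because there is 1 group. Comparisons under other settings of gene lists, muscle and stress levels and the muscle-score covariate were not run, as no identifier has a gene name, nor were modules of genes past the threshold, of which there were 0.

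The count of 0 genes with excess spread (edgeR, 696 at an unadjusted p of 0.05, under the share that chance alone would pass) stayed at 0 under other scalings, filters, covariates, a non-robust trend and restored RPKM, and from 0 to 0 with each library left out. In these settings the estimated prior degrees of freedom were 2.58 to 3.37. At 3.70 in simulated counts the test called 0 of 92 and 0 of 57 changed genes. The stable 0 is thus a limit of the test and no sign of even expression. DESeq2 dispersion outliers gave 110; the cause was not tested. RPKM as deposited gave 39 (pseudocount 0.1) and 28 (pseudocount 1) against 0 with restored RPKM, so these calls depended on the deposited divisors. The estimated prior degrees of freedom were 9.47 as deposited and 3.12 restored (pseudocount 0.1). Whether the genes called vary widely in the counts was not tested. The coefficient of variation was 0.325, 0.259 with the 2 runs as a covariate, and 0.303 to 0.334 with each library left out. The 543 genes with an SD of at least 1 became 1576 without a filter and 1317 with a filter in 3 libraries. The genes that enter there lay under the main filter's minimum in at least 1 library. The count was 361 with component 1 as a covariate, and 419 to 625 with each library left out. The first component took 47.3% at a mean CPM of at least 5 (fewer genes tested) and 41.3% to 46.1% with each library left out. The 10 highest genes took 18.3% of RPKM as deposited and 18.2% restored, against 16.6% of counts, as length enters. The 170 genes of module 1 became 109 without replicate 3 and at most 198 with another library left out; 107 of the 109 were members of module 1. The 5007 genes separating the runs became 1729 with RPKM as deposited against 4811 restored, and 5183 to 5742 with each library left out, where chance gives 1.59% in place of 0.794% because 4 against 5 part more easily. Depth limits rare genes most: a count of 0 allowed up to 0.129 CPM in the shallowest library.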

Other observations

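Chosen after the result was seen were the count over splits, the test on unscaled shares, the look at labels for batches, the depth test of module 1 and the module lengths; the other tests were written down before their results. The implied gene lengths gave a median of 2817 bases over the tested genes. Module 3 had a median of 3193 bases, above 99.99% of random lists matched on level (median 2016), and it was the only one of 11 modules above 95%; module 1 had 2753 bases, at 79.2%.

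The sample codes run from 74 to 78 in replicates 1 to 5 and from 80 to 84 in replicates 6 to 10, and 5007 of 16829 genes (29.8%) had levels that did not overlap between these sets, against 0.794% by chance. The split was noticed on component 1, and the labels give both sets the same perturbation. Of 100 splits of the libraries into 5 and 5, taken from 126 possible and including the one by code, 1 gave as many, the one by code itself. The highest other of those taken gave 580. Because the split was noticed in the same data, its rank alone says little. It falls on the gap in the codes, which is 1 of 126 possible splits. The gap was linked to the split only after the split was seen, so 1 of 126 is not a chance rate. The number was 4923 after thinning all libraries to the smallest total and 4893 after removing a smooth trend over gene length and level, which argues against depth or length bias as the whole cause; library totals also overlapped between the sets, at 23206247 to 36398252 and 26329657 to 37149070. A few abundant genes would shift the unscaled shares of all others one way, but outside the 100 most abundant 3335 genes lay in one direction and 1451 in the other. Both are above 580, which was counted on scaled values over both directions. No count of other splits on unscaled shares is given. That many genes lay in each direction argues against a few abundant genes as the whole cause. Leaving those 100 out before scaling gave 5010, which decides nothing as scaling already removes such a shift. A batch in handling, library preparation or sequencing may be the source. It cannot be told apart from a difference between the fish or in their treatment, as 0 label fields besides the title differ between libraries.

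A candidate source for the range of module 1 was a cell population or tissue that entered the samples in different amounts. In the 7 pairs of libraries with totals within 5% of each other, the module's unscaled share of counts differed by 1.39-fold to 22.3-fold (median 9.36). All 7 folds lay beyond the 1.14-fold range of the scaling factors. Libraries of like depth thus differed in this module, which argues against depth as the whole cause. The pairs share libraries, so they are not 7 separate tests. Members were chosen for a wide spread of scaled levels, so for scaling the outcome was set by that choice and decides nothing. When each member was fitted as a constant plus a multiple of the other members, the median residual SD was 0.511 (0.462 to 0.562), against a median SD of 0.345 and an upper quartile of 0.509 over all tested genes. Written beforehand, a value no larger than the median SD was to count for a single population, and a value over the upper quartile against it. By that rule the result counts against a single population, and the whole interval lies above 0.345. The margin over 0.509 is smaller than the interval, but weighing the interval was a criterion added after the value was seen. The result against a single population is therefore a narrow one.

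A further hypothesis was that genes with consecutive identifier numbers vary together. Over 12071 pairs the mean r was 0.0024, and 0.00907 after removal of 3 components, below the 0.0139 at the 95th percentile of 1000 random pairings, so these data gave no sign of it.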
